A study of Homo sapiens with 8 samples.

How the data were processed

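Human mesenchymal stem cells in 4 groups were measured on 8 arrays, 2 for each group: untransduced cells, cells given the backbone virus, and the low and high signal fractions of cells given the triple reporter lentivirus. Groups were taken from the sample titles. The series text names a green and the sample labels a red fluorescent protein in the reporter, and the labels of the high fraction also speak of a lower intensity. The sample labels and titles were followed. The deposited values are signal intensities per probe set, made by the authors with GCOS 1.2 per the submitters' processing notes. The algorithm and the target of its scaling are not given in the sources used here. The table holds 54675 probe sets with linear signals from 0.00257 to 2973, and the 2% trimmed means of the 8 arrays lie between 14.93 and 14.94, so the deposited scaling was kept. Raw probe intensities were not used here.

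Each signal was taken as log2 after adding 0.808, which is the median of all values divided by 4. The 62 control probe sets and 95 sex-linked probe sets were left out. A probe set was kept when the second-highest of its 8 signals exceeded the median of all values, 3.23, which left 32284. Of all probe sets 41097 carried 1 gene symbol, 1801 several and 11777 none, and only those with 1 symbol were tested, each gene by the kept probe set with the highest mean, which gave 14569 genes. Groups were compared with limma 3.58.1 in R 4.3.3. A mean per group was fitted over all 8 arrays, contrasts were tested with its moderated statistic and an intensity trend in the prior variance, and p-values were adjusted by Benjamini-Hochberg within each of the 6 comparisons with a threshold of 0.05. All tests were two-sided. The residual degrees of freedom were 4 and the prior degrees of freedom 4.30. With 2 arrays per group no permutation of arrays can reach that threshold, so no other splits were counted.

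The 26 gene lists cover responses to virus and stress, proliferation, metabolism, matrix, differentiation and markers of other cell types, and were tested in each comparison, 156 list tests in all. They were tested with camera at its preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists of a comparison. Members past the threshold were counted adjusted over all genes and adjusted over the list alone. The comparisons, the tests, the lists and the rule for naming genes were fixed before the data were examined. The rule names, in each comparison, the 12 largest rises and the 12 largest falls among called genes whose arrays do not overlap between the groups, up to 4 called members of each list, and a few surface and control genes. Where no gene passed, it names the 10 lowest p-values. Unnamed transcripts and genes with common deletions or alleles that affect probes are passed over. This gave 467 named calls. Of these, 234 had several kept probe sets, 51 had 1 or more with the opposite sign, and 3 had one called in the opposite direction.

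The method was tested on simulated data with 200 changed genes: it recovered 51% of the 2-fold and 86% of the 4-fold changes, made 150 calls of which 9 were false, and found the shifted list with 0 false calls among 26 lists. In a check for mixed-up samples, the arrays of 1 of the 4 groups did not match each other. The alternatives tried were other offsets, quantile normalization, centring on the median, no filter and a stricter one, every probe set or their mean in place of 1 per gene, other variance models, a 2-fold minimum, a threshold of 0.01, fits of only the 2 groups compared, a block for the replicate number, and leaving out each array. Fits with 1 array left in a group assume that it varies like the arrays of the other groups.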

Results

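RNA of human mesenchymal stem cells was measured on 8 oligonucleotide arrays (HG-U133 Plus 2.0), 2 for each of 4 groups. Untransduced cells formed the control group, and another group received a virus with the vector backbone and no reporter. The other 2 groups received a lentivirus with a triple reporter of luciferase, a monomeric red fluorescent protein and a thymidine kinase. Those cells were exposed to virus for 36 hours at a multiplicity of infection of 16, were sorted at a fluorescence of 1000 and grew for 1 passage. They are called the reporter-low and reporter-high groups here, after the signal fraction in their labels. The labels do not say that the backbone group was sorted, and the untransduced cells had no treatment, so any effect of sorting is part of the comparisons of the reporter groups with untransduced cells and may be part of those with backbone cells. Each array received 3 µg of RNA. The number of arrays limits the precision of every value, and nothing states whether the 2 arrays of a group came from separate cultures or donors, so the p-values measure only the spread between arrays. Each value below is a log2 difference between group means with its standard error (SE) and 2 arrays per group. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over 14569 genes, and a gene counts as changed at an adjusted p under 0.05. Where the mean signal of 1 of the groups lay under 3.23, the median of all values, the difference is given only as a lower bound on the fold. For it, signals under 3.23 were taken as 3.23. This bound allows for dim signals only. It still holds any array-wide shift, such as that of the reporter-high arrays described below. In every gene named as changed, both arrays of one group lay above both of the other.

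The arrays of the backbone pair and of the reporter-low pair resembled each other closely, with correlations across genes of 0.977 and 0.976. The 2 untransduced arrays resembled each other less, at 0.952. The first of them was closer to the reporter-low arrays (0.964 and 0.965) and the second to the backbone arrays (0.975 and 0.976). The reporter-high arrays correlated at 0.95 with each other and at 0.894 to 0.911 with the arrays of other groups. Their median signals were 4.64 and 4.38, against 2.71 to 2.95 elsewhere. Control spikes added at hybridisation followed the same split, with mean signals of 112 to 120 on the first untransduced and the reporter-low arrays, 84.3 to 94.0 on the second untransduced and the backbone arrays, and 206 and 208 on the reporter-high arrays. The labels give no batch, so groups and any batch of array processing cannot be told apart beyond the values given below for each untransduced array alone. Genes are not independent replicates in these correlations.

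**Figure D1:**
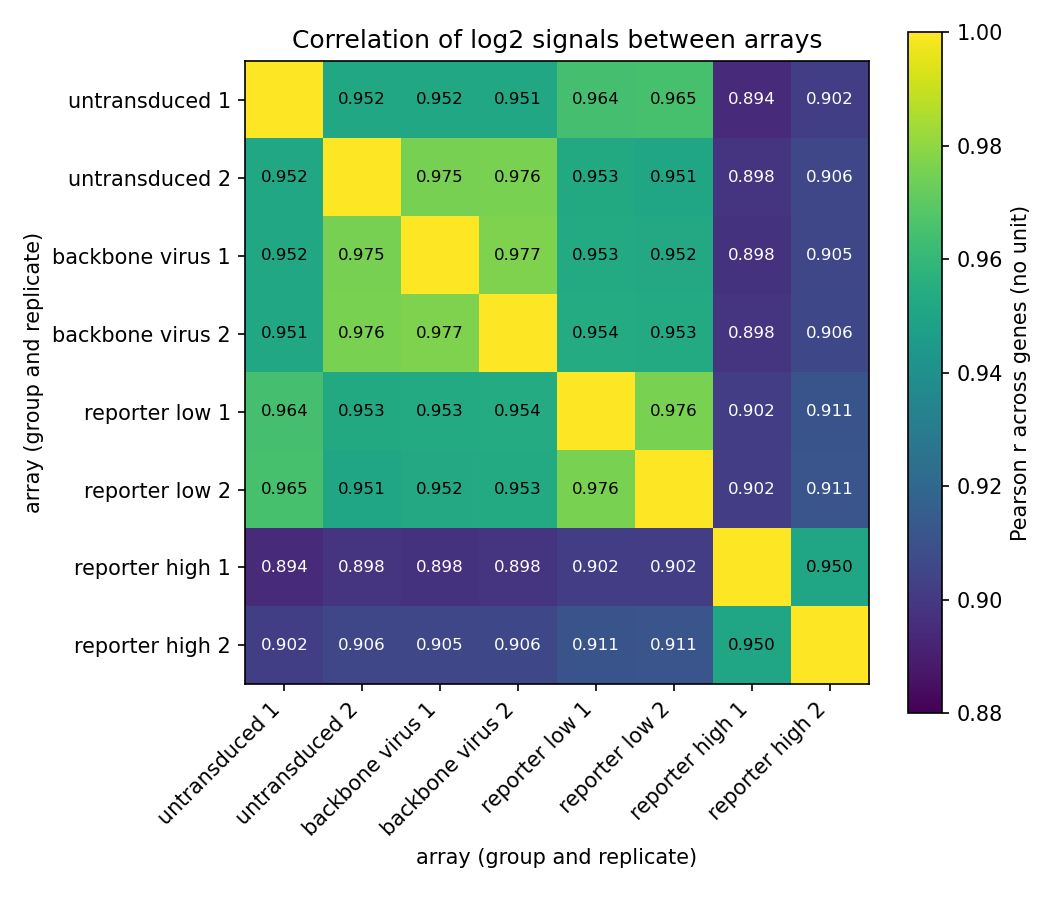
Pearson correlation of log2 signals across genes between each pair of the 8 arrays (axes: arrays by group and replicate; colour: r, no unit). The 2 reporter-high arrays reach at most 0.911 with an array of another group, and untransduced array 1 reaches 0.965 with reporter-low array 2.

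The backbone group against untransduced cells asks what the virus does without its reporter. The lowest p-values belonged to SPATA24 (0.81 ± 0.14 SE), ANO7 (at least 2.56-fold higher) and CACNB1, a calcium channel subunit (at least 2.17-fold lower), each with an adjusted p of 0.72. The surface proteins that define mesenchymal stem cells showed no call either: NT5E (CD73) differed by -0.24, THY1 (CD90) by -0.12, ENG (CD105) by 0.15 and CD44 by -0.20. No gene passed in limma (0 of 14569), and 826 had an unadjusted p under 0.05. Camera, a test of gene lists against all other genes, called 10 of 26 lists. The lowest p-values among them belonged to unfolded protein response genes (34 genes, median 0.21, adjusted p 2.25e-06) and matrix genes (46 genes, median 0.19, adjusted p 3.97e-07), with an adjusted p = 0.543 for both with an estimated correlation. Fry, which tests whether a list's genes move one way on balance, called 0 lists. The result depended on the untransduced array used. Without the second one, 2127 genes passed (1222 higher, 905 lower), and without the first, 3 genes did. These were GRK5, ACACB and IGHG1, all higher, named here after their values were seen. Without the first untransduced array the unfolded protein response list had a median of 0.03 (adjusted p 0.23) and the matrix list one of 0.05 (adjusted p 0.0123, but adjusted p = 0.528 with an estimated correlation). Without the second, the medians were 0.40 and 0.27.

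The reporter-low group against untransduced cells asks what the reporter virus and sorting do at a low reporter level. NEFM, a neurofilament subunit of nerve cells, rose by 3.02 ± 0.39 SE (adjusted p 0.0254), and SCUBE3, a secreted signalling protein, rose by 2.23 ± 0.18 SE (adjusted p 0.00518). S100A4, a calcium-binding protein of motile mesenchymal cells, rose from a mean signal of 25.8 to 85.0 (1.69 ± 0.11 SE, adjusted p 0.00228). Among the falls, COL14A1, a collagen of fibril surfaces, changed by -1.78 ± 0.16 SE (adjusted p 0.00518), and MGP, an inhibitor of calcification, by -1.67 ± 0.21 SE (adjusted p 0.0237). RUNX2, the transcription factor that starts bone formation, changed by -1.24 ± 0.17 SE (adjusted p 0.0317). CLU, a secreted chaperone, changed by -1.81 ± 0.12 SE (adjusted p 0.00228). In all, 56 of 14569 genes changed, 33 up and 23 down, 30 of them at least 2-fold, while 1777 had an unadjusted p under 0.05. The count was 0 without the variance trend, 0 with only these 2 groups fitted and 29 with a block for the replicate number. Among surface proteins NT5E rose by 0.87 ± 0.12 SE (adjusted p 0.0317), the tetraspanin CD151 by 0.77 ± 0.09 SE and the adhesion molecule ALCAM by 0.55 ± 0.08 SE. THY1 (0.16), ENG (0.17) and CD44 (0.37) were not called.

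Genes of the response to low oxygen and of glycolysis were higher in the reporter-low cells as a list (30 genes, median 0.32, camera adjusted p 1.25e-12, adjusted p = 0.0328 with an estimated correlation). This was the only one of the 49 list calls made over the 6 comparisons that held with an estimated correlation. Its called members were ADM, a vasodilator peptide (0.88 ± 0.10 SE), and BNIP3, a mitophagy receptor (0.54 ± 0.07 SE). Over all genes 2 members passed, and 13 passed when adjusted over the list alone, all higher. The median was 0.32 with the first untransduced array alone and 0.29 with the second alone, where the adjusted p with an estimated correlation was 0.0854 and 0.131. Mesenchymal surface genes were higher (26 genes, median 0.19, adjusted p 1.75e-05, but adjusted p = 0.0965 with an estimated correlation), with 3 members called over all genes and 7 higher and 1 lower adjusted over the list alone. Their median was 0.25 with the first untransduced array alone (adjusted p = 0.0922 with an estimated correlation) and 0.08 with the second alone (adjusted p = 0.294 with an estimated correlation). Heat shock genes were also higher (16 genes, median 0.19, adjusted p 1.82e-05, but adjusted p = 0.346 with an estimated correlation). Of these, the small heat shock proteins CRYAB (0.97 ± 0.12 SE) and HSPB1 (0.71 ± 0.09 SE) rose over all genes and 4 did adjusted over the list alone, while with the first untransduced array alone the list had a median of 0.12 (adjusted p 0.10) and with the second alone one of 0.44. Osteogenic genes were lower (19 genes, median -0.19, adjusted p 0.0113, but adjusted p = 0.146 with an estimated correlation), though their median was -0.31 with the first untransduced array alone and -0.10 (adjusted p 0.195) with the second alone.

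Interferon-stimulated genes were higher in the reporter-low cells by camera (44 genes, median 0.22, adjusted p 3.18e-05, but adjusted p = 0.348 with an estimated correlation). IFIT1, which binds foreign RNA, was the only member that passed over all genes (1.21 ± 0.14 SE, adjusted p 0.014), and 4 were higher adjusted over the list alone. The list's median was 0.43 with the first untransduced array alone and 0.04 (adjusted p 0.864) with the second alone. The matrix list was lower (median -0.23, adjusted p 0.0129, but adjusted p = 0.495 with an estimated correlation), with 2 members lower over all genes and 5 higher and 13 lower adjusted over the list alone. It had a median of -0.02 (adjusted p 0.798) with the first untransduced array alone, and of -0.15 (adjusted p 0.057) without the first reporter-low array. All 56 genes kept their direction against each untransduced array alone. They had been called against both, and such a fit leaves out the spread between the untransduced arrays, so this adds no support. The count fell to 0 without either reporter-low array, to 9 without the first backbone array, and to 10 without the second backbone array or without either reporter-high array, since all 8 arrays share 1 estimate of spread.

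The reporter-high group against untransduced cells asks the same at a high reporter level. HMGA2, a chromatin protein of embryonic and growing cells, rose by 2.86 ± 0.16 SE (adjusted p 8.1e-05), and F2RL2, a protease-activated receptor, rose from a mean signal of 4.61 to 51.8 (3.31 ± 0.22 SE, adjusted p 0.000122). FABP4, a fatty-acid carrier of fat cells, rose at least 4.89-fold (adjusted p 0.00676). MGP changed by -2.73 ± 0.21 SE (adjusted p 0.000227), COL14A1 by -2.37 ± 0.16 SE (adjusted p 0.000122) and SFRP4, a secreted Wnt inhibitor, by -2.91 ± 0.45 SE (adjusted p 0.00398). The growth factors IGF1 (at least 4.17-fold, adjusted p 0.0125) and FGF7 (-1.65 ± 0.12 SE, adjusted p 0.00017) were lower, and FGF5 was higher (1.46 ± 0.21 SE, adjusted p 0.00273). RNF5 (at least 18.1-fold) and IGF2BP3 (at least 9.20-fold) rose as well, and their signals were graded with the reporter: RNF5 had means of 0.758 in untransduced, 6.55 in reporter-low and 58.4 in reporter-high cells, and the other probe set of IGF2BP3 had 2.21, 3.03 and 10.0. In all, 3907 genes changed, 2211 up and 1696 down, 1606 of them at least 2-fold.

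Interferon-stimulated genes were higher in the reporter-high cells (44 genes, median 1.04, adjusted p 1.2e-07, but adjusted p = 0.719 with an estimated correlation). IFIT3 rose by 2.57 ± 0.25 SE, IFIT2 by 2.55 ± 0.26 SE and IFIT1 by 2.37 ± 0.14 SE, and MX2, a restriction factor for lentiviruses, by 1.21 ± 0.19 SE. Over all genes 25 members passed and 28 did adjusted over the list alone, all higher. Cell cycle genes were higher as well (57 genes, median 0.85, adjusted p 1.46e-12, but adjusted p = 0.235 with an estimated correlation). They included the centromere histone CENPA (1.83 ± 0.25 SE), the mitotic ubiquitin enzyme UBE2C (1.68 ± 0.24 SE) and the mitotic kinesin KIF20A (1.61 ± 0.16 SE). Over all genes 38 passed, and 41 adjusted over the list alone, none lower. The cell's own thymidine kinase TK1 rose by 1.12 ± 0.17 SE. The cell cycle inhibitor CDKN1A rose too (1.00 ± 0.07 SE, adjusted p 0.00017), while the inhibitor CDKN2B changed by -1.60 ± 0.16 SE. Both lists kept their camera call in each refit that left out 1 array, but the interferon list had a median of 1.27 with the first untransduced array alone and of 0.63 (17 higher, 3 lower) with the second alone, and the cell cycle list one of 1.00 and 0.76.

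Oxidative stress and metallothionein genes were higher in the reporter-high cells (24 genes, median 0.42, adjusted p 0.0058, but adjusted p = 0.352 with an estimated correlation). GPX3, a secreted peroxidase, rose by 2.04 ± 0.11 SE, and the metal-binding proteins MT1F and MT1H by 1.59 ± 0.20 SE and 1.32 ± 0.10 SE. Over all genes 11 members were higher and 3 lower, and 12 and 3 adjusted over the list alone. Matrix genes were lower (median -0.40, adjusted p 0.00126, but adjusted p = 0.808 with an estimated correlation), with 10 higher and 24 lower over all genes and 11 and 25 adjusted over the list alone. With the first untransduced array alone this list had a median of -0.34 and an adjusted p of 0.158. Low-oxygen and glycolysis genes were lower (median -0.29, adjusted p 0.0362, but adjusted p = 0.383 with an estimated correlation), such as ANKRD37 (-1.66 ± 0.15 SE) and the glycolytic enzyme GPI (-0.77 ± 0.08 SE). Here 4 members were higher and 8 lower over all genes, and 5 and 10 adjusted over the list alone. The list had an adjusted p of 0.124 with the second untransduced array alone and of 0.0913 without the second reporter-high array.

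Of the surface proteins, THY1 changed by -0.80 ± 0.08 SE (adjusted p 0.000677) and ENG by -0.66 ± 0.11 SE (adjusted p 0.00493), while CD44 rose by 0.66 ± 0.12 SE (adjusted p 0.00714). The control gene ACTB was 0.68 higher than in untransduced, 0.33 higher than in reporter-low and 0.62 higher than in backbone cells, and quantile normalization gave -0.27 in each case, a sign fixed by rank because ACTB had the highest signal on each of the other arrays. The matrix gene COL1A1 went from 0.70 to -0.18 under it. GAPDH was 0.95 higher, and 0.10 (adjusted p 0.399) after quantile normalization. The share of higher genes depended on the scaling and the filter. With each array centred on its median, 4702 genes changed in the reporter-high cells against untransduced cells, 30.4% of them higher, in place of 56.6%, and the median of all genes moved from 0.07 to -0.14. A stricter filter on low signals left 1271 higher and 1638 lower. The count was 1514 without the first reporter-high array and 1948 without the second, and 3213 and 3136 of the 3907 genes passed in the same direction against the first and the second untransduced array alone.

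**Figure D2:**
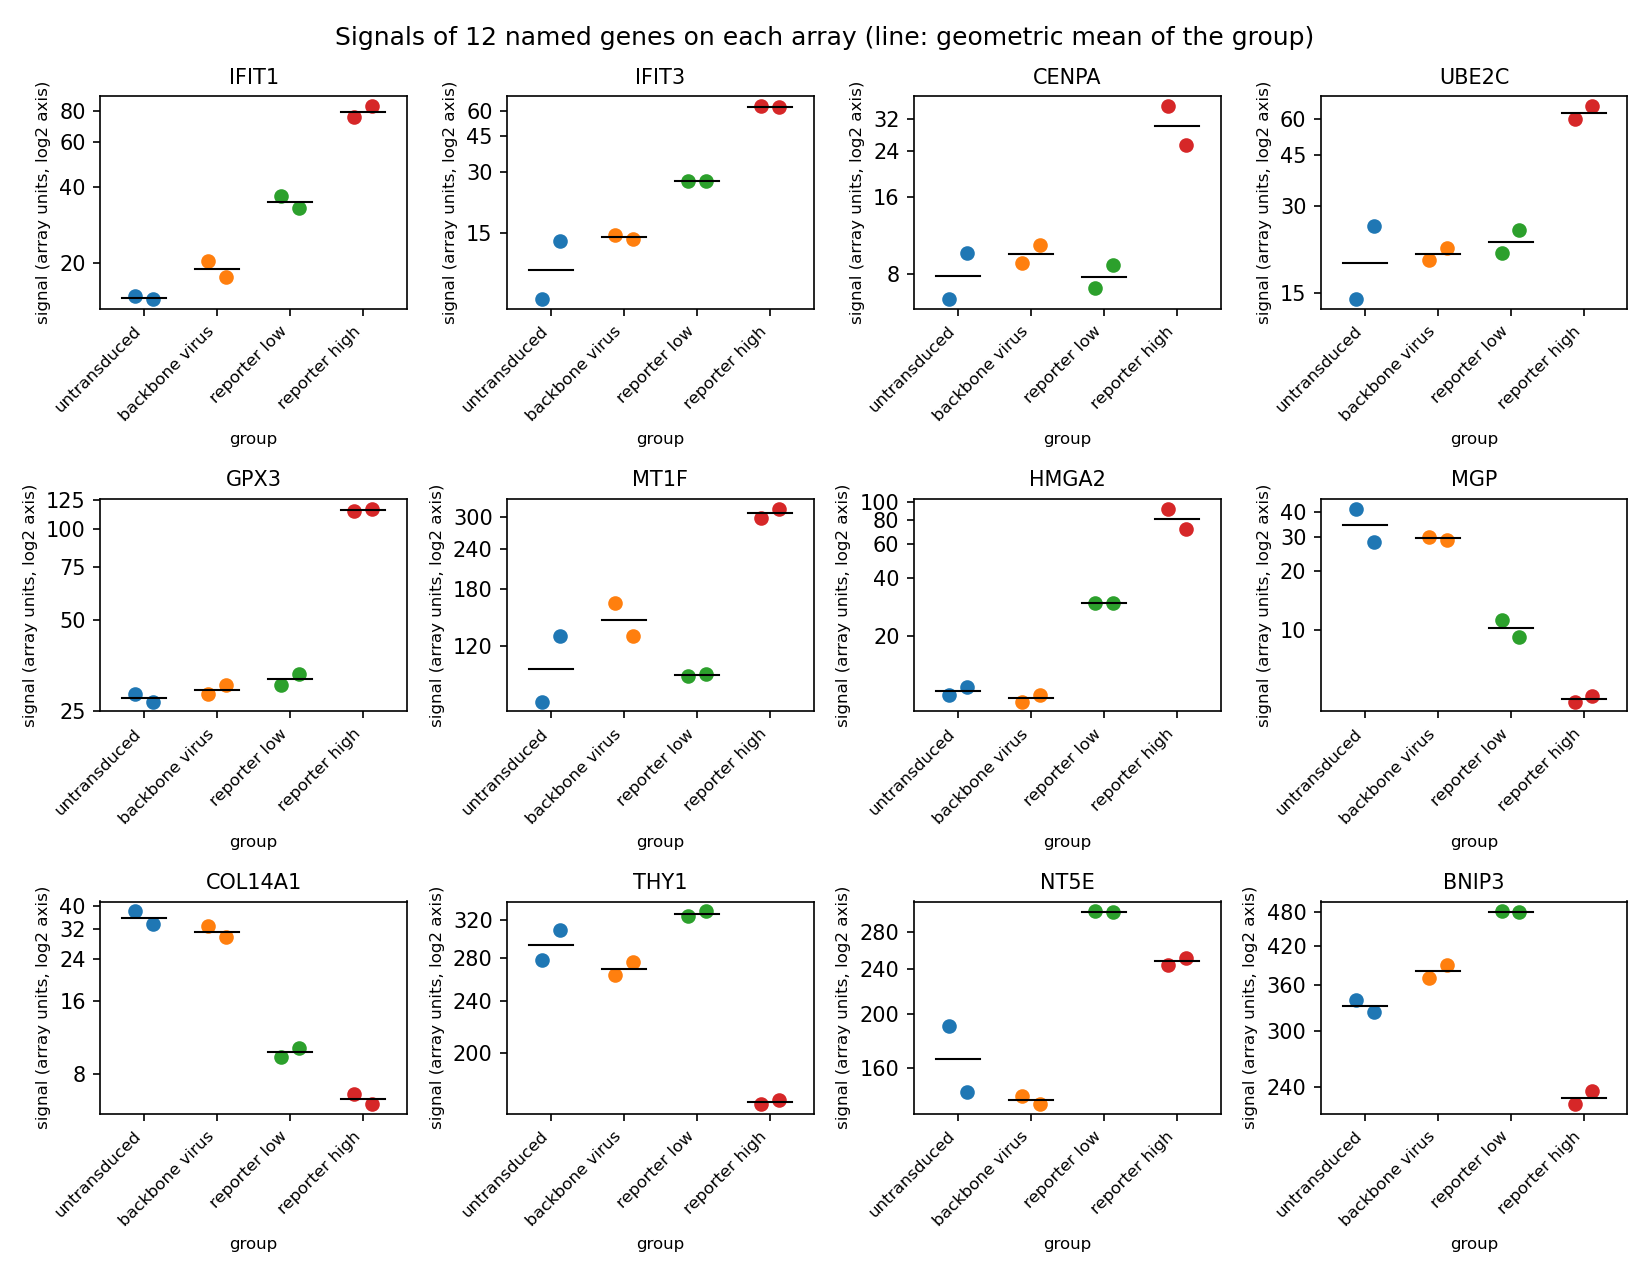
Signals of 12 named genes on each of the 8 arrays (log2 axis, array units; points: arrays, lines: geometric mean of the 2 arrays of a group). HMGA2 and IFIT1 are higher in reporter-low and higher again in reporter-high cells, whereas BNIP3 has a mean of 331 in untransduced, 480 in reporter-low and 230 in reporter-high cells.

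The reporter-high against the reporter-low group compares reporter levels among sorted cells. MX1, an interferon-induced antiviral GTPase, was 2.30 ± 0.30 SE higher (adjusted p 0.00214), CENPA 1.84 ± 0.25 SE higher (adjusted p 0.00253), GPX3 1.84 ± 0.11 SE higher (adjusted p 0.000301) and HMGA2 1.42 ± 0.16 SE higher (adjusted p 0.00122). Genes lower with more reporter included BST1, a surface enzyme of marrow stroma (-3.38 ± 0.39 SE, adjusted p 0.00138), and the contractile genes SYNPO2 (-2.74 ± 0.46 SE, adjusted p 0.00547), LMOD1 (-1.89 ± 0.13 SE, adjusted p 0.000341) and CNN1 (-1.40 ± 0.21 SE, adjusted p 0.00337). The smooth muscle list as a whole was not called (28 genes, median -0.03, adjusted p 0.41), with 4 members higher and 6 lower over all genes and 5 and 6 adjusted over the list alone. THY1 (-0.96 ± 0.08 SE), CD151 (-0.94 ± 0.09 SE) and ENG (-0.83 ± 0.11 SE) were lower as well. In all, 4314 genes changed, 2564 up and 1750 down. With each array centred on its median there were 5040, with 30.8% higher in place of 59.4%, and the median of all genes moved from 0.11 to -0.13. The stricter filter left 1255 higher and 1649 lower.

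The low-oxygen and glycolysis list was lower in the reporter-high than in the reporter-low cells (30 genes, median -0.62, adjusted p 8.19e-09, but adjusted p = 0.0692 with an estimated correlation). ANGPTL4, a lipase inhibitor, changed by -2.12 ± 0.33 SE, ANKRD37 by -1.40 ± 0.15 SE and BNIP3 by -1.06 ± 0.07 SE. Over all genes 2 members were higher and 19 lower, and 2 and 20 adjusted over the list alone. Interferon-stimulated genes were higher (median 0.75, adjusted p 0.000489, but adjusted p = 0.80 with an estimated correlation), with 19 members over all genes and 21 adjusted over the list alone. Cell cycle genes (median 0.84, adjusted p 2.66e-10) and oxidative stress genes (median 0.53, adjusted p 0.000196) were higher, each with an adjusted p = 0.111 with an estimated correlation. Of the cell cycle genes 37 were higher over all genes and 41 adjusted over the list alone, and of the oxidative stress genes 13 in both. The mesenchymal surface list was lower (median -0.20, adjusted p 0.0487, but adjusted p = 0.331 with an estimated correlation). It was not called without the first or the second backbone array (adjusted p 0.0514 and 0.0515), the second reporter-low array (0.0617) or the second reporter-high array (0.122). The count of changed genes was 1320 without the first reporter-low array, 1414 without the second, 1657 without the first reporter-high array and 2220 without the second.

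The reporter groups against the backbone group ask what the reporter cassette adds to the virus. The labels give no virus dose, exposure time, sorting or passage for the backbone group, so these may differ as well. In the reporter-high cells SPP1, the bone matrix protein osteopontin, was 3.28 ± 0.52 SE higher (adjusted p 0.00393), FABP4 at least 4.99-fold higher (adjusted p 0.00346) and ISG15, an interferon-induced ubiquitin-like protein, 2.09 ± 0.16 SE higher (adjusted p 0.000248). RARRES2, the adipokine chemerin, was at least 13.6-fold lower (adjusted p 0.00438), and the chemokine-scavenging receptor ACKR3 changed by -3.60 ± 0.48 SE (adjusted p 0.00193). COMP, a cartilage matrix protein, changed by -2.40 ± 0.41 SE (adjusted p 0.00515). In all, 4295 genes changed, 2306 up and 1989 down. With each array centred on its median there were 5029, with 29.1% higher in place of 53.7%, and the median of all genes moved from 0.07 to -0.15. The stricter filter left 1273 higher and 1925 lower. The count was 1285 without the first backbone array, 1348 without the second, 1670 without the first reporter-high array and 2224 without the second.

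As lists in the reporter-high against the backbone cells, interferon-stimulated genes (median 0.73, adjusted p 2.97e-05, but adjusted p = 0.587 with an estimated correlation) and cell cycle genes (median 0.85, adjusted p 1.14e-11, but adjusted p = 0.268 with an estimated correlation) were higher. Oxidative stress genes were higher too (median 0.45, adjusted p 0.015, but adjusted p = 0.347 with an estimated correlation). Matrix genes (median -0.53, adjusted p 1.69e-06) and unfolded protein response genes (median -0.43, adjusted p 0.000263) were lower, each with an adjusted p = 0.587 with an estimated correlation. The unfolded protein response list had a median of 0.19 in reporter-high cells against the first untransduced array alone and of -0.35 against the second. The sign of its median thus depended on the array compared with. The low-oxygen and glycolysis list was lower (median -0.23, adjusted p 0.00855, but adjusted p = 0.347 with an estimated correlation). Of the interferon list 18 members were higher and 1 lower over all genes, and 19 and 2 adjusted over the list alone. Of the matrix list 7 were higher and 25 lower, and 7 and 26 adjusted over the list alone.

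In the reporter-low cells against the backbone cells, NEFM was at least 10.5-fold higher (adjusted p 0.00631), IL6, an inflammatory cytokine, 1.00 ± 0.09 SE higher (adjusted p 0.00509) and the neurotrophin BDNF 1.54 ± 0.21 SE higher (adjusted p 0.0183). NT5E was 1.12 ± 0.12 SE higher (adjusted p 0.00877). PTGDS, a prostaglandin synthase, changed by -3.83 ± 0.47 SE (adjusted p 0.0128), COL15A1, a basement membrane collagen, by -2.96 ± 0.37 SE (adjusted p 0.0134) and RUNX2 by -1.63 ± 0.17 SE (adjusted p 0.00824). In all, 172 genes changed, 82 up and 90 down, against 7 without the variance trend, 3147 with only these 2 groups fitted and 81 with a block for the replicate number. The matrix list was lower (median -0.35, adjusted p 5.83e-07, but adjusted p = 0.268 with an estimated correlation), with 9 lower over all genes and 2 higher and 20 lower adjusted over the list alone. Low-oxygen and glycolysis genes were higher (median 0.21, adjusted p 1.4e-06, but adjusted p = 0.127 with an estimated correlation), with 2 over all genes and 14 higher and 1 lower adjusted over the list alone. Unfolded protein response genes were lower (median -0.43, adjusted p 2.03e-05, but adjusted p = 0.322 with an estimated correlation), with 0 over all genes and 1 higher and 16 lower adjusted over the list alone. The first untransduced array lay below the second by a similar amount (median -0.41, and -0.24 for the matrix list), and against the first alone the list was higher in reporter-low cells (median 0.17, adjusted p 0.000344, but adjusted p = 0.0922 with an estimated correlation). The count of changed genes was 0 without any single backbone or reporter-low array, 44 without either reporter-high array, and 2498 and 2508 without the first and the second untransduced array.

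**Figure D3:**
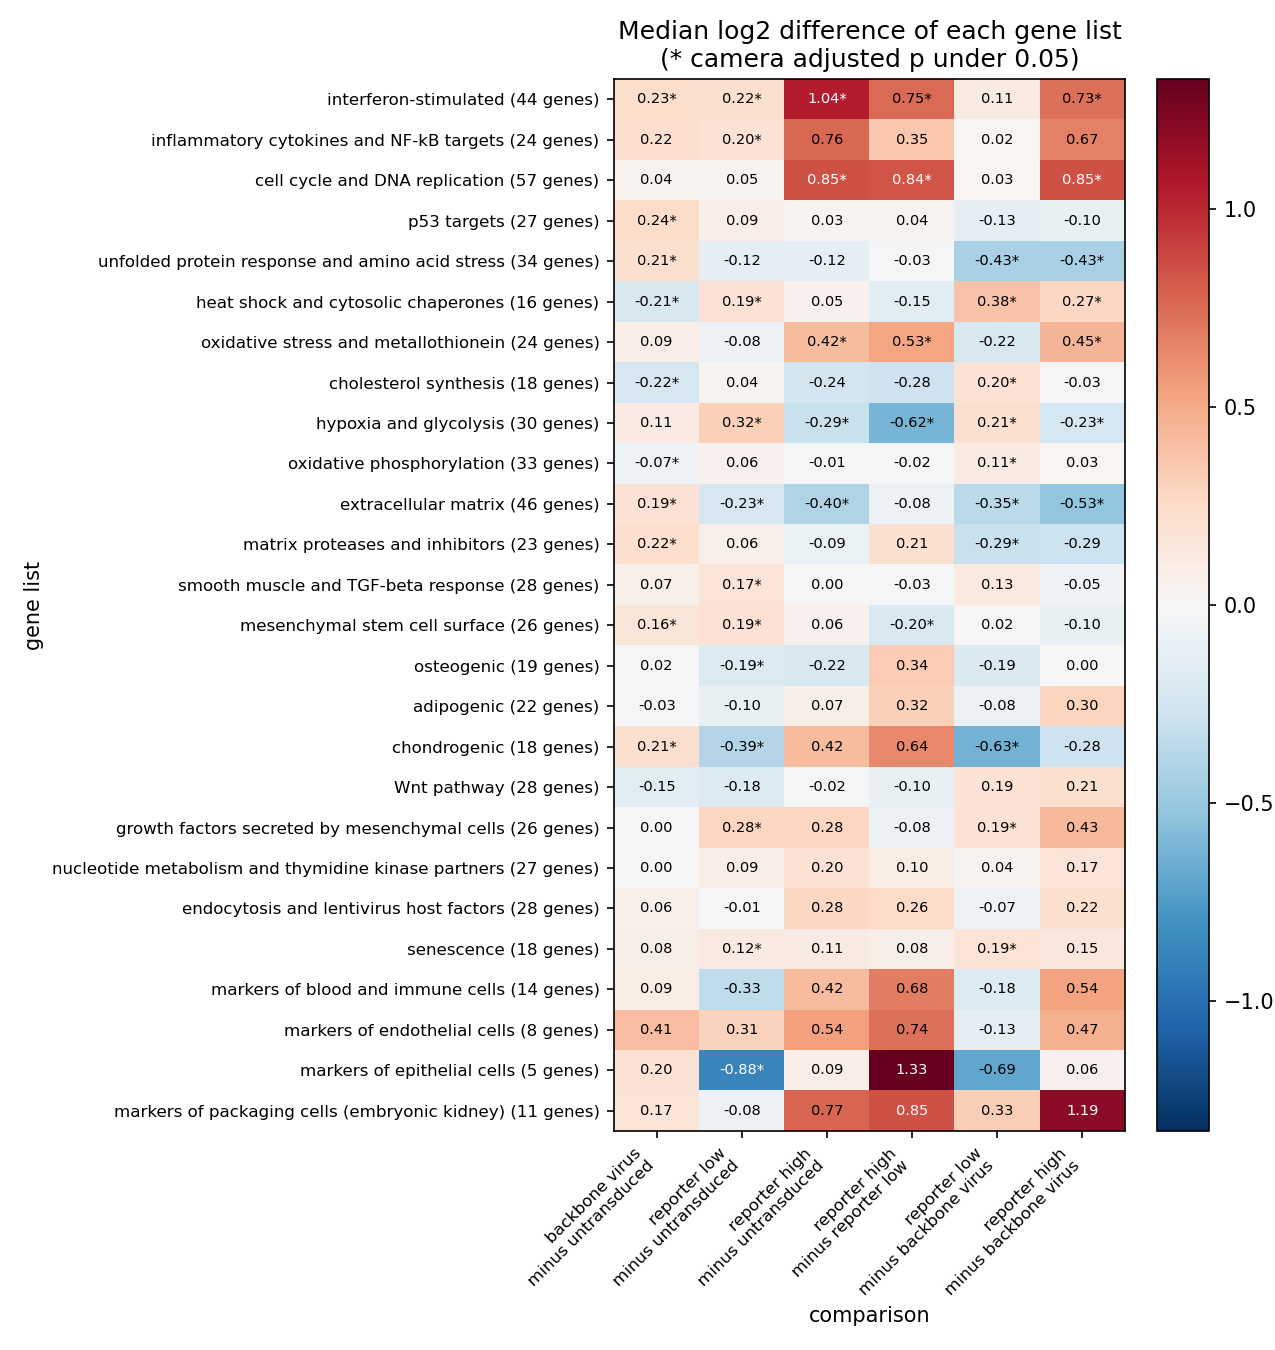
Median log2 difference of each of 26 gene lists (vertical axis, with the number of genes) in the 6 comparisons (horizontal axis); asterisks mark a camera adjusted p under 0.05. The low-oxygen and glycolysis list is at 0.32 in reporter-low and -0.29 in reporter-high cells against untransduced cells, and the interferon list at 0.22 and 1.04.

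Against untransduced cells, 41 genes were called in both reporter groups, 34 of them in the same direction and 7 in opposite directions. Lists drawn independently would share 7.7 genes in the same direction. Both comparisons use the same 2 untransduced arrays. In 100 simulations without effects, sharing them gave the log2 differences a correlation of 0.501, and the observed one was 0.222. Effects, absent from the simulations, widen the observed differences and can lower a correlation, so these 2 values are not a like comparison. The covariance was 0.0678 observed and 0.0485 simulated. In 20 simulated refits the lists shared at most 1 gene. Data without effects hold few genes to call, so this cannot show how many calls the shared arrays alone would give lists of this length. Over the 4 groups together, 3907 genes differed in the F test of limma at an adjusted p under 0.05. Leaving out 1 array moved this count in every case: to 6671 and 7172 for the first and second untransduced array, 1651 and 1590 for the backbone arrays, 1645 and 1649 for the reporter-low arrays and 714 and 961 for the reporter-high arrays.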

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

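All the tests of explanations in this part were chosen after the results they bear on had been seen.

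Among the 54518 probe sets examined, including those without a gene symbol that no comparison used, 14 stood at least 16-fold above every array without reporter in both reporter-high arrays and at least 2-fold above in both reporter-low arrays. They drew attention as a signal graded with the reporter, in probe sets that no comparison used except that of IGF2BP3. That probe set is the one tested for IGF2BP3 in the comparisons above. The brightest of them, which carries no gene symbol, had mean signals of 2621 in reporter-high and 289 in reporter-low cells and at most 4.18 elsewhere. One annotated to COX6A1, a subunit of cytochrome oxidase, had 695, 46.1 and at most 0.436, whereas the other probe set of COX6A1 had 383 in reporter-high, 465 in reporter-low and 463 in untransduced cells. The hybridisation control spikes, another measurement no comparison used, had geometric means of 206 and 208 on the reporter-high arrays against 112 to 120 on the first untransduced and the reporter-low arrays and 84.3 to 94.0 on the second untransduced and the backbone arrays. The low-oxygen and glycolysis list is included because its effect against untransduced cells went opposite ways, with a median of 0.32 in reporter-low and -0.29 in reporter-high cells. The rule for including a list also required a camera call in reporter-high minus reporter-low cells, so that call adds no support. There the median was -0.62 (camera adjusted p 8.19e-09, adjusted p = 0.0692 with an estimated correlation).

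The first pattern is the graded probe sets, and a candidate explanation is that their probes pair with the reporter transcript. Of the 18 probe sets 16-fold higher in reporter-high cells, 77.8% also rose in both reporter-low arrays, but those are the ones that define the pattern, so this decides nothing about pairing. The brightness of the reporter-high arrays would leave these probe sets unchanged in reporter-low cells. The median of all 18 there was 2.24 above the first untransduced array. The 14 that define the pattern carry such a rise by definition, so this value alone decides nothing about brightness. The median signals of the arrays were 2.95 and 2.88 in untransduced, 2.71 and 2.79 in reporter-low and 4.64 and 4.38 in reporter-high cells. The 14 probe sets rose by a median of 6.06 in log2 from untransduced to reporter-high cells, far more than those array medians differ. This argues against array-wide brightness alone for the 14. A rise of the 5 genes that the annotation names is argued against by the other 8 probe sets of the same genes, whose median difference was -0.12 (quartiles -0.19 and 0.16), although that of IGF2BP3 went from 2.21 to 10.0. The sequences of the probes and of the vector were not used here, so pairing stays untested, and the named genes RNF5 and IGF2BP3 may carry such signal.

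The second pattern is the difference between the 2 untransduced arrays, of which 20 genes were at least 8-fold apart, among them the secreted proteins GREM1, FBLN1 and AEBP1, named here after their values were seen. A difference in array-wide scale alone is argued against by the similar signals of the 2 arrays, with medians of 2.95 and 2.88 and 25th percentiles of 0.850 and 0.855. All 20 stayed 8-fold apart after quantile normalization, but it moves such similar arrays little, so that adds no support. The difference between the 2 arrays recurred between reporter-low and backbone cells, with a correlation of 0.505 over 14569 genes, as 2 cell or culture backgrounds spread over the groups would give. The same arrays split by the hybridisation spikes (lowest of the first set 0.26 in log2 above the highest of the second) and by a 28S ribosomal RNA probe set (46.8 to 74.9 against 16.1 to 18.0), as shared array processing or RNA preparation would give. Both stay open, calls between reporter-low and backbone cells may in part reflect them, and beyond such backgrounds, which the labels do not name, no biological explanation was tested.

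The third pattern is the excess of higher genes on the reporter-high arrays (2211 against 1696 lower, compared with untransduced cells), whose median signals and spikes were also higher, and which the stricter filter turned into 1271 higher and 1638 lower. For genes with a mean signal below 3.23 on the other 6 arrays, which the filter can admit on the 2 reporter-high arrays alone (567 higher, 5 lower), 30.2% of the higher calls were kept after quantile normalization, so a raised floor may account for many of these. Of the higher calls among genes from there to the 75th percentile (766 higher, 162 lower) 54.8% were kept, which leaves the floor open, and among brighter genes 85.5%, which argues against the floor for those, although they do not hold the excess (878 higher, 1529 lower). Degraded RNA is argued against by a ratio of 3' to 5' GAPDH signal of at most 1.04 on these arrays, but their 28S ribosomal RNA signals of 126 and 111 exceeded the 16.1 to 74.9 of the others, so a difference in RNA preparation stays open. A cell or culture background of its own cannot be told apart from the reporter level, because no array of another group shares it (highest correlation 0.911) and both reporter-high arrays would carry it.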

How the results depend on the processing

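The tests without both reporter-high arrays and with each array centred on its median were chosen after seeing the data. The count of 0 for backbone against untransduced cells held in limma under every alternative that kept both untransduced arrays. Offsets and the robust variance model kept every count of changed genes within 1.5 times. Of the 467 named calls, 443 and 465 were kept with no offset and with an offset at the median, 403 after quantile normalization, 438 with centring, 384 with the mean of a gene's probe sets and 337 without the variance trend. Leaving out 1 array kept between 270 (first reporter-high array) and 462 (first untransduced array). Of the 49 list calls 47 were kept after quantile normalization, 40 with the stricter filter and 35 without the first untransduced array, where 4 reversed. The causes of the changes below were not tested, except where the setting itself, through fewer arrays, more tests or a stricter threshold, shows the cause.

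Leaving out each array in turn gave 0 to 2127 genes for backbone against untransduced cells, 1514 to 4826 for reporter-high and 0 to 1769 for reporter-low against untransduced cells, 1320 to 6328 for reporter-high against reporter-low, 1285 to 6162 for reporter-high and 0 to 2508 for reporter-low against backbone cells, 714 to 7172 for the F test and 44 to 56 list calls. Without both reporter-high arrays 10 genes passed in reporter-low against untransduced and 44 against backbone cells. With only the 2 groups compared, these were 0 and 3147, and 1072 for reporter-high against untransduced cells. With no variance trend they were 0 and 7, and the F test gave 2551. With no filter 99 and with the stricter filter 262 genes passed in reporter-low against backbone cells. With the mean of probe sets 34 passed in reporter-low against untransduced cells. Every probe set tested gave 7313 for reporter-high and 96 for reporter-low against untransduced cells, 8367 for reporter-high against reporter-low, 8147 and 322 for reporter-high and reporter-low against backbone cells, and 7085 for the F test. In the same order, a 2-fold minimum gave 1606, 30, 1915, 1793 and 101, and a threshold of 0.01 gave 1275, 7, 1390, 1413 and 28, with 1047 for the F test. With an estimated correlation 1 list call held, and fry made 53.

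A block for the replicate number gave 29 genes for reporter-low against untransduced cells and 81 against backbone cells, and 3416 for reporter-high against untransduced cells. The numbers are not stated to pair the arrays, and the replicate differences of 2 groups correlated at -0.034 to 0.023 across genes, so no pairing was seen.

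Quantile normalization turned ACTB to -0.27 in all 3 reporter-high comparisons, which its top rank on each of the other arrays fixed and which says nothing about the gene. It also turned SERPINE2 to -0.17 and COL1A1 to -0.18 against untransduced cells. The stricter filter, which chose another probe set, turned MMP16 to 0.11 and 0.48 in reporter-low against untransduced and backbone cells. The mean of probe sets turned SREBF2 to 0.14 and 0.20 in reporter-high against untransduced and backbone cells, MYL9 to 0.022 against reporter-low cells, and ME1 to 0.37 in reporter-low against backbone cells. Leaving out 1 untransduced array reversed list medians. In backbone against untransduced cells they ranged from -0.026 without the first to 0.42 without the second for interferon genes, from -0.44 without the second to 0.063 without the first for heat shock, from -0.42 to 0.099 for cholesterol synthesis and from -0.18 to 0.0082 for oxidative phosphorylation. In reporter-low against untransduced cells they ranged from -0.35 without the first to 0.17 without the second for unfolded protein response genes, from -0.19 without the second to 0.23 without the first for cholesterol synthesis and from -0.33 without the first to -0.021 without the second for matrix genes, where the test changed sign but not the median. Signal over background limits genes below 3.23, where a difference between dim signals depends on the offset and on each array's floor.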

Other observations

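The tests of lists and genes in this part were fixed in advance, but the genes that moved in opposite directions were singled out after their values were seen.

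Of the 7 genes called in opposite directions in the 2 reporter groups against untransduced cells, 4 with known roles were higher in reporter-low and lower in reporter-high cells. IL6, an inflammatory cytokine, was at 0.87 and -0.33, CHI3L1, a secreted glycoprotein of cartilage and inflammation, at 1.10 and -0.89, BNIP3 at 0.54 and -0.52, and the membrane protein MYADM at 0.52 and -0.47. PENK, the precursor of enkephalin peptides, and AKR1C1, a steroid-reducing enzyme, went the other way, at -1.37 and 0.96 and at -0.60 and 0.32. The direct comparison of reporter-high with reporter-low cells was called in limma for each. Opposite calls against the same untransduced cells make that call nearly certain, so it adds no support. Among the genes named here the direct difference ran from 2.34 for PENK (adjusted p 0.00021) to -2.00 for CHI3L1 (adjusted p 0.000521). An unnamed transcript among the 7 was at 3.14 (adjusted p 0.000366).

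Of 27 genes of nucleotide supply, 6 were higher and 2 lower in reporter-high than in untransduced cells, over all genes and adjusted over the list alone, and the list was not called by camera (median 0.20, adjusted p 0.475) but was by fry (adjusted p 0.00345). The higher ones included TK1, the ribonucleotide reductase subunit RRM2 (1.03 ± 0.11 SE), CAD, which starts pyrimidine synthesis (1.02 ± 0.16 SE), and thymidylate synthase TYMS (0.85 ± 0.12 SE). Fat-cell genes went both ways, with the fatty-acid carrier FABP5 at 1.67 ± 0.14 SE, the protease adipsin, CFD, at least 2.06-fold lower and the desaturase SCD at -1.40 ± 0.23 SE. The apoptosis effector BAX was 1.69 ± 0.18 SE higher, while p53 targets as a list had a median of 0.03 (adjusted p 0.79). With the first untransduced array alone that median was 0.23 (adjusted p 0.0388, but adjusted p = 0.307 with an estimated correlation), and with the second alone -0.11 (adjusted p 0.527). Each of these genes stayed called when any 1 array was left out.

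Lists of markers of other cell types were not called by camera in reporter-high against untransduced cells: blood and immune cells (14 genes, adjusted p 0.29), endothelial cells (8 genes, adjusted p 0.798), epithelial cells (5 genes, adjusted p 0.822) and virus packaging cells (11 genes, adjusted p 0.533). In the same order, 3, 2, 1 and 3 members were higher and 0, 2, 1 and 2 lower over all genes, and 3, 3, 2 and 5 higher and 0, 2, 1 and 2 lower adjusted over the list alone. The endothelial marker PECAM1 (1.24 ± 0.19 SE) and the keratin KRT19 (1.23 ± 0.17 SE) rose, and the endothelial receptor TEK changed by -1.63 ± 0.20 SE. Fry called the blood list (adjusted p 0.00833) and the packaging list (adjusted p 0.0119) as higher. It does not set a list against other genes. Genes with a mean signal below 3.23 on the other 6 arrays rose by a median of 0.91 here. The packaging marker GATA3 (mean 2.04 in untransduced cells) was such a gene, so these calls may in part reflect that rise. The epithelial list was called lower in reporter-low against untransduced cells (median -0.88, adjusted p 0.0388, but adjusted p = 0.272 with an estimated correlation), with 0 members called. It was not called without the second reporter-low array (adjusted p 0.0515) or the first or second reporter-high array (0.0648 and 0.0649).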
